A study of Mus musculus with 2 samples.

How the data were processed

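The series holds gene expression from nuclei of mouse gastrocnemius, a mixed leg muscle dominated by fast fibres, measured with the gene expression part of a combined chromatin and expression droplet kit, per the labels. There were 2 libraries, 1 of innervated muscle of wild-type mice without treatment and 1 of muscle taken 7 days after denervation. Per the labels' protocols, each library was made from 3 to 4 muscles pooled before the nuclei were released, the muscles had been snap-frozen, and nuclei were sorted by flow cytometry on an antibody against the nuclear pore complex that stains all nuclei. Each condition thus had 1 library and no replicate, and the muscles of a pool could not be told apart. The chromatin part of the kit was not used here.

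The deposited values are raw UMI counts per gene and barcode, where a UMI (unique molecular identifier) marks 1 captured RNA molecule. Per the submitters' processing notes the counts were made with Cell Ranger ARC 2.0.0 on the mouse build mm10, while per the file headers the matrices were written by cellranger 7.2.0; both are stated because they differ. The annotation, the barcode filter and whether reads in introns were counted are not given in the sources used here. The deposited counts cover 32285 genes, the same table in both libraries, with 5319 barcodes and 10748206 UMIs in the innervated library and 2365 barcodes and 8893803 UMIs in the denervated library. The deposited medians were 1572 and 2562 UMIs per barcode. Gene positions come from GENCODE vM21 on GRCm38, the assembly behind mm10, matched by Ensembl identifier.

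Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 10% of UMIs from mitochondrially encoded genes. The mitochondrial limit left out 21 innervated and 17 denervated barcodes, the gene limit 2 and 2, and the lowest deposited totals were 500 and 503 UMIs. Doublets were scored as the share of simulated doublets among the nearest neighbours of each barcode, and the highest scores were left out at a rate of 0.8% per 1000 barcodes, which took 225 innervated and 44 denervated barcodes. This left 5073 innervated and 2303 denervated nuclei. Both libraries were clustered together without integration (log-normalised counts, 2000 variable genes, 30 principal components, 20 nearest neighbours, Leiden resolution 1, seed 7).

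Clusters were named "X-like" from fixed markers, and the class names used in the text stand for such clusters. A class other than myonucleus needed 3 markers among the 50 leading genes of the cluster by fold. A remaining cluster was named myonucleus where 3 myonucleus markers, found in at least 10% of its nuclei, were at least 1.5-fold above the mean of the clusters of other classes. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed. This rule was set in its final form after the clusters had been seen, and it kept 1 cluster out of the myonuclei, with 9 innervated nuclei (0.177%) and 483 denervated nuclei (20.97%). That cluster was led by H19, Cdk8 and Gm26917, held the satellite cell marker Sdc4 among its leading genes, and carried Ttn at 88.4% of the myonuclear level in the denervated library. Sdc4 was the 1 marker that kept it from being named myonucleus. Sdc4 was itself higher in denervated myonuclei, as were Trim63 and Gadd45a, which were also among the leading genes of the cluster. The cluster may thus hold denervated myonuclei, which the main shares and folds leave out.

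UMIs of each gene were summed over the nuclei of a class in each library and divided by the summed UMIs of nuclear genes of that class, as counts per 1000000 (CPM). A fold is denervated over innervated. Intervals are exact 95% counting intervals: Poisson for a sum, Clopper-Pearson for a share and the conditional binomial interval for a fold. They cover counting error only. With 1 library per condition no test between conditions exists, so no p-value and no count of genes passing a test is given. No difference has a replicate check. Counts of genes at least 1.5-fold higher or lower describe these 2 libraries only. A fold against 0 UMIs was computed against a floor of 3 UMIs, over the class, and is written as a lower bound. Myonuclei with at least 3 UMIs over Myh1, Myh2, Myh4 and Myh7 were put in the class of the isoform with over 50% of them, otherwise mixed. This is a range of a score, not a fibre type, because the isoforms themselves differ between the libraries.

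The 24 gene lists cover acetylcholine receptor and postsynaptic genes, denervation regulators, atrophy and ubiquitin ligase genes, the proteasome, autophagy and lysosome, fast sarcomere, slow sarcomere, developmental muscle genes, fibre type regulators, glycolysis and glycogen, mitochondria and fat oxidation, excitation-contraction coupling, ion channels, costamere and membrane, polyamines, neurotrophic factors, matrix genes of fibroblast-like cells, Schwann cell repair and Schwann cell myelin genes, satellite cell state, immediate early and stress genes, clock genes, sex-linked genes and signs of free RNA. A list member counted as measured with at least 20 UMIs over both libraries in the class. For each list the median log2 fold of its measured members was taken, with an interval from Poisson resampling and the number of members at least 1.5-fold higher or lower. The percentile of its median among 10000 random lists matched on size and mean level was computed too. The text leaves out some intervals. Beside the results it gives the place among random lists for denervation regulators and fast sarcomere genes, both at an extreme, and for ion channel and costamere genes. Lists not at an extreme in myonuclei included ion channels (6.08), clock (20.2), neurotrophic (28.5), costamere (29.0), polyamine (36.9), immediate early (92.6) and autophagy genes (93.1). The medians of these lists do not stand out from those of random lists. The percentile describes these 2 libraries and tests no condition.

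The text names genes by a rule of 4 parts. Any measured list member may be named as an example. In myonuclei, the 12 highest and 12 lowest folds are named among genes with at least 100 UMIs over both libraries, at least 20 CPM in the higher library, the same direction in each majority class with at least 100 nuclei per library, no other class over 3 times the myonuclear level there, and a symbol that is not a placeholder. In any other class with at least 50 nuclei per library, the 5 highest and 5 lowest are named among genes with at least 30 UMIs, at least 50 CPM in the higher library and a level there not under that of myonuclei. Between the Myh4-majority and Myh2-majority classes, the 6 genes with the largest difference of log2 fold in each direction are named among those with at least 100 UMIs in both. Genes outside the rule are said to be so where they appear. Results of some genes are not reported here, and these genes are left out of the counts of genes with opposite folds.

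Lists, markers, filters, the named-gene rule and the settings listed next were written before the data were examined. The other settings tried were edgeR's TMM and DESeq2's size factors as scales, mitochondrial genes kept in the total, equal weight per nucleus, other limits on UMIs and mitochondrial share, no doublet removal, nuclei thinned to 1 depth (1018 UMIs), expected free RNA subtracted, majority classes set to their innervated shares, other minima for lists and rankings, muscle fibre genes left out of the total in fibro-adipogenic progenitors, Leiden resolutions 0.5 and 2, separate clustering, and a limit of 80% or 10 UMIs for majority classes. Keeping the unnamed cluster in the myonuclei and leaving Gm42418, Gm26917 and AY036118, which are ribosomal-like transcripts, out of the total were added after the data had been seen.

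The fold step was tested on simulated Poisson counts with the levels and depths of these libraries and 200 genes changed by known folds. These counts held no variation between nuclei or muscles, so the test checks the computation and not the intervals for real nuclei. In the myonucleus simulation of 7814 genes, the intervals held the true fold for 95.3% of genes, and of the 32 genes set to 0.5-fold 96.9% came out at least 1.5-fold lower. In the simulation of 2792 genes for fibro-adipogenic progenitors, the intervals held the true fold for 95.7%, and 90.6% of the 32 genes set to 0.5-fold came out at least 1.5-fold lower. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.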

Results

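Nuclear RNA was counted in 1 library of innervated and 1 library of denervated mouse gastrocnemius, the latter taken 7 days after the nerve supply had been removed. After filtering, the innervated library held 5073 nuclei and 9514503 UMIs, with a median of 1537 UMIs and 848 genes per nucleus. The denervated library held 2303 nuclei and 8447267 UMIs, with a median of 2539 UMIs and 1120 genes. Each library was a pool of several muscles and neither condition had a replicate, so all differences are differences between these 2 libraries. Higher and lower mean higher and lower in the denervated than in the innervated library, and brackets give 95% counting intervals. The title of the series concerns why fast muscle fibres are vulnerable in neuromuscular disease, and the comparison shows what fibres of a mostly fast muscle express without their nerve. Both libraries carried Xist, with 11852 UMIs in the innervated and 9811 in the denervated library, and 2 UMIs each from 4 Y-linked genes.

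The first comparison concerns which nuclei each library held. Clusters named as myonuclei, with markers such as Ttn, Neb and Dmd, which encode giant structural proteins of the fibre, made up 85.1% of innervated nuclei (4317 nuclei) [84.1 to 86.1] and 51.6% of denervated nuclei (1188 nuclei) [49.5 to 53.6]. Fibro-adipogenic progenitor-like nuclei, from connective tissue cells marked by Pdgfra and Dcn, were 10.2% (520 nuclei) and 9.51% (219 nuclei). Macrophage-like nuclei, marked by F13a1, Adgre1 and Cd163, were 0.651% (33 nuclei) [0.448 to 0.912] and 14.2% (327 nuclei) [12.8 to 15.7]. An unnamed cluster, which carried Ttn near the level of myonuclei and the markers Neb and Dmd but was led by other genes, held 0.177% of innervated and 20.97% of denervated nuclei. Its leading genes included Trim63 and Gadd45a, which were also higher in denervated myonuclei, so it may hold myonuclei. With this cluster counted as myonuclei, their denervated share was 72.6%. Smaller classes were the blood endothelial-like nuclei (78 innervated and 17 denervated), adipocyte-like (44 and 12), smooth muscle-like (31 and 24), satellite cell-like (29 and 11) and lymphatic endothelial-like nuclei (12 and 22). No cluster met the markers of Schwann cells or tenocytes.

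**Figure D1:**
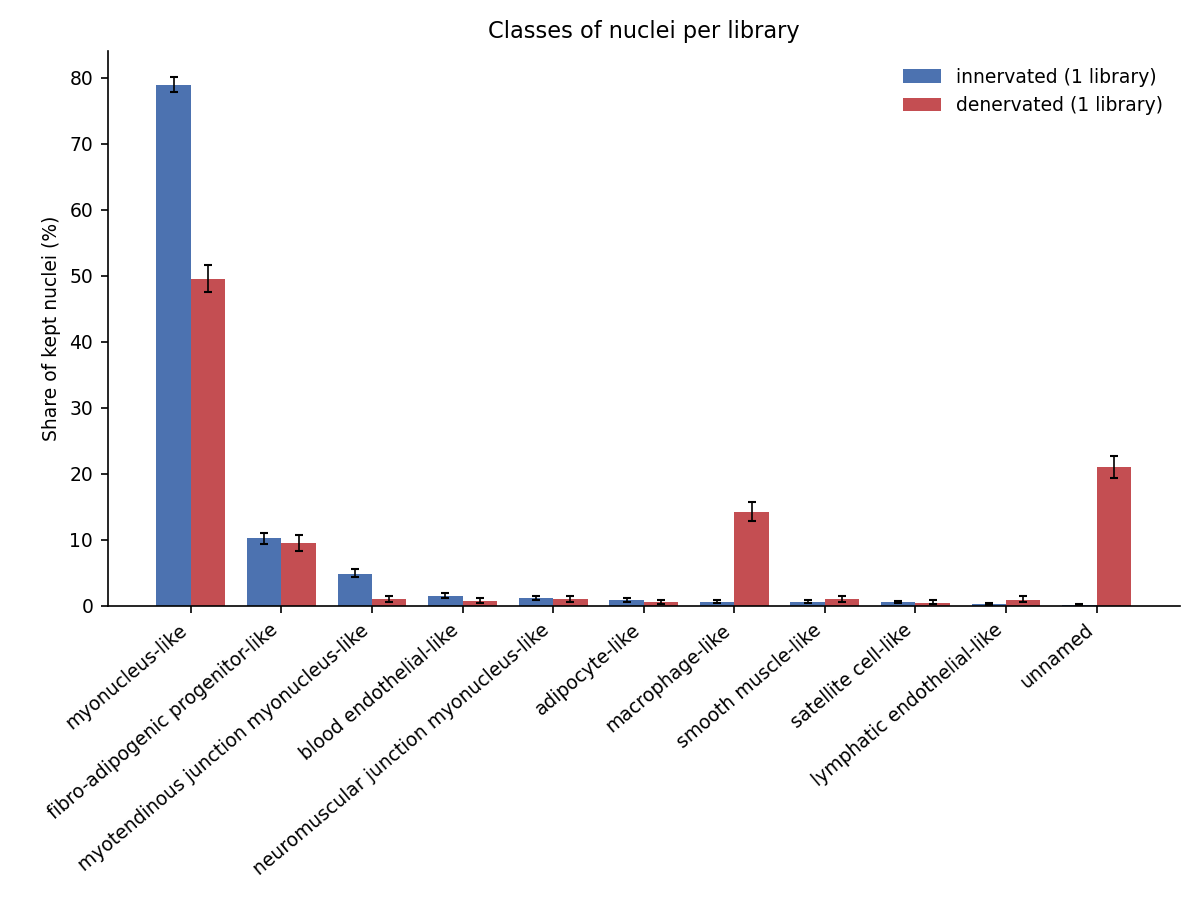
Share of kept nuclei in each class, in percent, for the innervated library (5073 nuclei) and the denervated library (2303 nuclei), with exact 95% binomial intervals as error bars. Macrophage-like nuclei were 0.651% and 14.2%, and the unnamed cluster was 0.177% and 20.97%.

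These shares depend on the clustering and on a depth gap, since myonuclei had a median of 1551 UMIs in the innervated and 3578 in the denervated library. The denervated share of myonuclei was 72.9% at Leiden resolution 0.5, 62.4% at resolution 2 and 65.1% with each library clustered on its own. The innervated share of myonuclei was lower with at least 1000 UMIs per nucleus, as given below. The denervated macrophage share was 5.21% at Leiden resolution 0.5 and 4.78% at resolution 2, and the denervated share of fibro-adipogenic progenitors was 18.8% at resolution 0.5. With each library clustered on its own, the macrophage shares were 0% and 5.21%. The macrophage-like cluster was mixed in the denervated library, where Ttn stood at 65.7% of the myonuclear level and 47.4% of its nuclei held at least 3 UMIs of macrophage markers [41.9 to 53.0]. Without clusters, 2.84% of all innervated nuclei [2.40 to 3.33] and 13.7% of all denervated nuclei [12.3 to 15.1] held at least 3 such UMIs, at median depths of 1537 and 2539 UMIs. Among myonuclei 1.41% and 10.4% did, at median depths of 1551 and 3578 UMIs. The count without clusters therefore does not read macrophages alone. Sorting was on a nuclear pore antibody and favoured no class by design.

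Myosin heavy chains, the motor proteins that define fibre types, are the plainest readout of the fibre programme. Myh4, the chain of the fastest (type IIb) fibres, was 11.3-fold lower in denervated myonuclei [10.8 to 11.9], at 3315 CPM in the innervated and 292 CPM in the denervated library. Myh1, the chain of type IIx fibres, was 2.06-fold lower [1.94 to 2.18]. Myh2, of type IIa fibres, was 1.38-fold higher [1.31 to 1.47], and Myh7, of slow fibres, 3.05-fold higher [2.52 to 3.70]. The embryonic chain Myh3 was 46.7-fold higher on 3 and 96 UMIs [15.5 to 231], and the neonatal chain Myh8 6.57-fold higher [3.00 to 16.4]. The 6 chains together were 4.00-fold lower [3.89 to 4.12], so Myh4 made up 79.1% of myosin UMIs in the innervated and 27.9% in the denervated library.

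**Figure D2:**
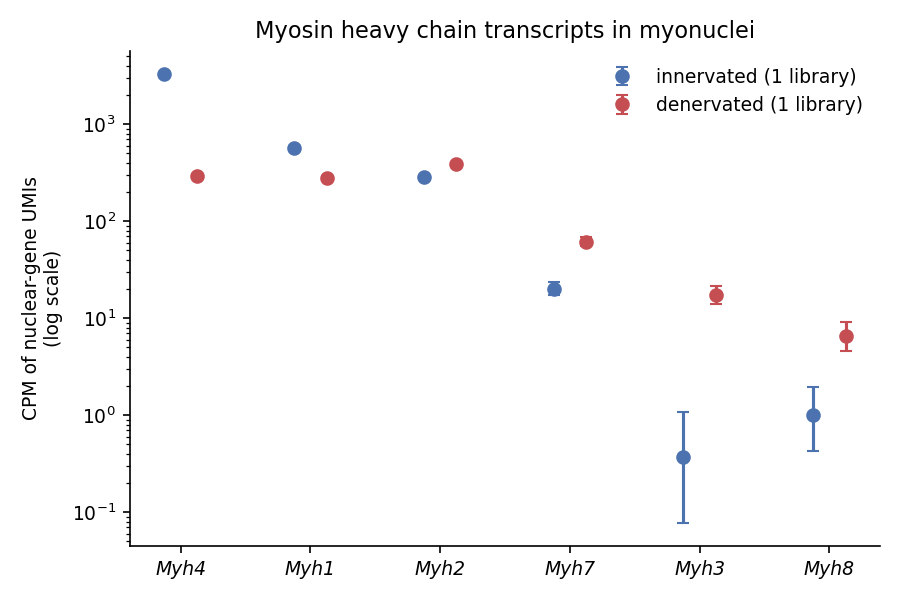
Myosin heavy chain transcripts in myonuclei, in CPM on a log axis, for the innervated library (4317 myonuclei) and the denervated library (1188 myonuclei), with exact 95% Poisson intervals as error bars. Myh4 stood at 3315 and 292 CPM, and Myh3 at 0.373 and 17.4 CPM.

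Counted by nucleus, 89.1% of innervated and 26.6% of denervated myonuclei had a Myh4 UMI, and 87.4% and 15.0% did after thinning to 1018 UMIs, which left out 761 and 56 nuclei. In fibro-adipogenic progenitors, which should lack Myh4, the shares were 43.5% and 7.31% at median depths of 1340 and 1357 UMIs, and 53.0% and 4.41% after thinning, so the denervated share in myonuclei lay above background. Of myonuclei with at least 3 myosin UMIs, 85.6% of 3627 had a Myh4 majority in the innervated library and 40.5% of 343 in the denervated library. A Myh2 majority was held by 4.88% and 30.6%, a Myh1 majority by 7.86% and 21.0%, and a Myh7 majority by 0.358% and 5.25%. The Myh2-majority shares were 2.07% and 18.95% at a limit of 80%, and 9.01% and 41.6% with at least 10 myosin UMIs required. In the innervated library 16.0% of myonuclei had fewer than 3 myosin UMIs, against 71.1% in the denervated library, and 97 and 30 nuclei lay within 10 points of the limit of 50%. With majority classes set to their innervated shares, the log2 fold of Myh4 was -1.49 against -3.50 in the pooled myonuclei, which follows in part from classes defined by the Myh4 they retained. The denervated share with a Myh4 majority was 24.4% after thinning and 25.9% with at least 10 myosin UMIs required.

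In the second comparison, the same 4317 innervated and 1188 denervated myonuclei were compared gene by gene. They came from different clusters, the innervated ones mostly from clusters 0, 1, 2, 6 and 7 and the denervated ones mostly from clusters 3 and 9. Over the 7824 genes with at least 100 UMIs the median log2 fold was -0.10. All folds compare shares of the myonuclear UMIs of a library, not amounts per nucleus. Myonuclei had median depths of 1551 innervated and 3578 denervated UMIs, so a lower share need not mean fewer UMIs per nucleus.

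Denervation regulators went both ways, with 9 of 16 measured genes at least 1.5-fold higher, 6 lower and a median log2 fold of 1.80 [1.32 to 2.10]. Runx1, a transcription factor that preserves denervated muscle, was 76.3-fold higher [61.6 to 95.8], at 10.6 and 807 CPM. Gadd45a, a stress gene that changes chromatin in denervated fibres, was 36.9-fold higher [27.4 to 50.9], the myogenic factor Myog 31.3-fold [14.8 to 79.2] and the deacetylase Hdac4, an early step of the denervation response, 3.55-fold [3.42 to 3.69]. Among the lower members were Hdac9 (6.64-fold), Dach2 (4.75-fold) and myostatin, Mstn (6.48-fold). The list median stood above all 10000 random lists, and fell to 1.07 when list members of any depth were kept and to 1.14 after thinning.

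Receptor and postsynaptic genes went both ways, with 7 of 16 at least 1.5-fold higher, 5 lower and a median log2 fold of 0.45 [0.28 to 0.61], or 0.80 at innervated class shares. The foetal acetylcholine receptor subunit Chrng was 140-fold higher [24.6 to 5593] on 1 and 96 UMIs, the subunits Chrna1 and Chrnb1 were 16.0-fold [9.71 to 28.0] and 9.57-fold higher [7.85 to 11.8], the receptor-clustering kinase Musk 4.97-fold and the adhesion molecule Ncam1 14.3-fold. The adult subunit Chrne was 1.97-fold lower, the collagen tail Colq 1.99-fold and the synaptic transcription factor Etv5 2.27-fold lower. Colq, Etv5 and Chrne are also markers of the junction cluster, and outside that cluster Colq and Etv5 were higher.

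Atrophy genes were higher, with 11 of 17 at least 1.5-fold higher, 1 lower and a median log2 fold of 0.84 [0.66 to 1.17]. The muscle ubiquitin ligases Fbxo32 (atrogin-1) and Trim63 (MuRF1) were 11.7-fold [11.1 to 12.3] and 3.66-fold higher [3.56 to 3.77], reaching 2535 and 2971 CPM. A Fbxo32 UMI was found in 18.6% of innervated and 74.6% of denervated myonuclei after thinning (26.1% and 85.6% before), and in 6.10% and 23.5% of thinned fibro-adipogenic progenitors (11.2% and 26.5% before). The proteasome list had a median log2 fold of 0.34 [0.31 to 0.47] with 9 of 32 subunits at least 1.5-fold higher and 0 lower, led by Psmd14 at 2.46-fold. Autophagy and lysosome genes had a median of 0.16 [0.00 to 0.22], or -0.01 at innervated class shares, with 2 of 20 higher, among them the protease Ctsl at 3.10-fold, and 2 lower.

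The contractile lists moved apart. Of 16 fast sarcomere genes 15 were at least 1.5-fold lower and 0 higher, with a median log2 fold of -1.86 [-2.06 to -1.79], below all 10000 random lists. The fast myosin-binding protein Mybpc2 was 39.3-fold lower [33.2 to 46.8], the kinase Mylk4 30.8-fold, the calsequestrin Casq1 8.52-fold and the calcium buffer Pvalb 5.89-fold lower. Of 15 slow sarcomere genes 10 were higher and 3 lower, with a median of 1.08 [0.89 to 1.33], which was 0.51 at innervated class shares and 1.58 after thinning. Csrp3, a stretch-linked Z-disc protein, was 63.3-fold higher [31.8 to 148], Lmod2 3.48-fold and Tnnt1 3.03-fold, while Myl2 was 2.31-fold lower. Developmental muscle genes had a median of 2.53 [2.15 to 2.95] with 9 of 12 higher, such as the embryonic troponin Tnnt2 at 5.11-fold and the imprinted Peg3 at 5.10-fold, and 2 lower, the imprinted Meg3 at 23.9-fold among them. The median was 1.95 when list members of any depth were kept and 3.07 after thinning.

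Most measured genes of energy metabolism made up a lower share of myonuclear UMIs. Glycolysis and glycogen genes had a median log2 fold of -2.23 [-2.25 to -2.18], with 21 of 26 lower and 2 higher. Lactate dehydrogenase Ldha was 23.3-fold lower, the enolase Eno3 16.7-fold, phosphofructokinase Pfkm 7.82-fold and glycogen phosphorylase Pygm 4.91-fold lower, while the branching enzyme Gbe1 was 1.60-fold higher. Of 32 mitochondrial and fat oxidation genes 22 were lower and 2 higher, with a median of -1.07 [-1.17 to -0.97]. The mitochondrial creatine kinase Ckmt2 was 10.0-fold lower and citrate synthase Cs 3.77-fold lower, while the fuel switch Pdk4 was 2.03-fold higher. Transcripts of the mitochondrial genome, which are free cytoplasmic RNA, ranged from mt-Co2, 1.35-fold lower, to mt-Nd1, 2.30-fold lower. In that list of 11 measured genes 6 were lower, among them Ckm at 11.6-fold, 2 were higher, the nuclear RNAs Malat1 (2.02-fold) and Neat1 (3.08-fold), and the median was -0.72, or -0.20 at innervated class shares, -0.37 after thinning and -2.07 with expected free RNA subtracted. In Myh4-majority nuclei the median of that list was 0.14, or -0.14 at a limit of 80%. The estimated share of free RNA in myonuclei, from markers of other cell types, was 11.5% in the innervated and 13.1% in the denervated library. An estimate from muscle fibre genes in fibro-adipogenic progenitors, given below, went the other way between the libraries.

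Regulators of fibre type were mostly lower, 15 of 28 against 3 higher, with a median log2 fold of -0.76 [-0.89 to -0.62]. Maf, a transcription factor that drives the type IIb programme, was 31.9-fold lower [27.5 to 37.2], the nuclear receptors Nr4a1 and Ppara 21.9-fold and 4.82-fold lower, and Ppargc1a, a regulator of mitochondrial genes, 2.54-fold lower. The factors Tead4 and Mef2a were 29.7-fold [24.1 to 37.1] and 6.34-fold higher. Excitation-contraction genes were lower in 10 of 16 and higher in 3, with a median of -0.89 [-0.94 to -0.84]. Jph1, which holds the junctional membranes together, was 5.33-fold lower and the calcium release channel Ryr1 2.33-fold lower, while sarcolipin, Sln, an inhibitor of the calcium pump, was at least 39.4-fold higher on 0 and 81 UMIs. Ion channels had 5 of 16 higher and 7 lower, with a median of -0.50 [-0.60 to -0.29]. The calcium-activated potassium channel Kcnn3 was 179-fold higher [116 to 294], while the chloride channel Clcn1 was 3.90-fold lower. Costamere and membrane genes went both ways, 5 of 20 higher and 6 lower, with a median of -0.26 [-0.33 to -0.17], or -0.13 at innervated class shares. The medians of the ion channel and costamere lists stood at percentiles 6.08 and 29.0 of random lists. Utrn, the relative of dystrophin, was 3.97-fold higher and Dag1 3.40-fold lower.

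**Figure D3:**
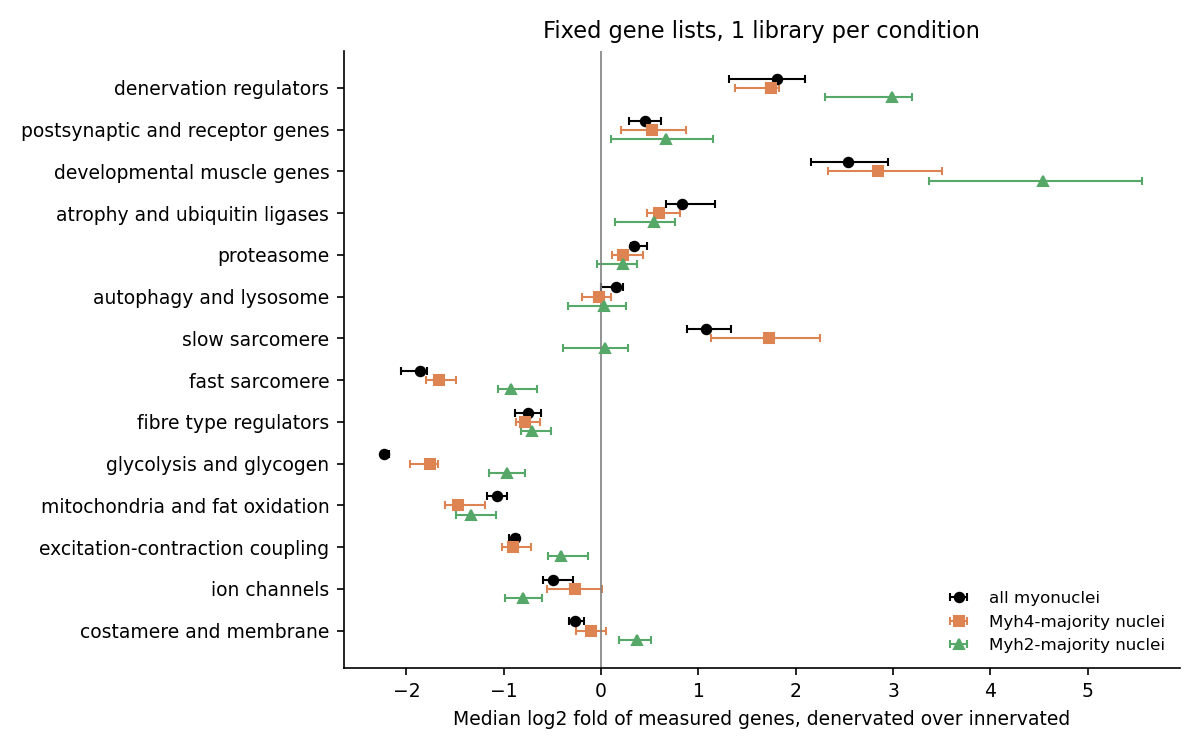
Median log2 fold, denervated over innervated, of the measured members of 14 gene lists in all myonuclei (circles), Myh4-majority nuclei (squares) and Myh2-majority nuclei (triangles), with 95% counting intervals as error bars. Fast sarcomere genes stood at -1.86, -1.66 and -0.93, and denervation regulators at 1.80, 1.74 and 2.99.

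By size alone, the 12 highest folds in myonuclei included those of Aif1l, Hhipl1, Kcnk5, Kcnn3, Ptgfrn, Ankrd1, Sh3d19, Pkhd1, Sh3rf1, H19 and Runx1, from 76.3-fold for Runx1 to 527-fold for Aif1l, which rested on 1 and 361 UMIs [94.0 to 20875]. The best covered were Sh3d19 with 37 and 3763 UMIs, 148-fold higher [108 to 211], and Kcnn3 with 20 and 2455 UMIs. Ankrd1 is a mechanically induced titin-binding protein that also served as a junction marker, and H19 an imprinted noncoding RNA that also led the unnamed cluster. The 12 lowest were Dhrs7c, Stc2, Mybpc2, Lrrc38, Ces1d, Myoz1, Maf, Mylk4, Rpl3l, Asb18, Tmem233 and Col4a3, from 59.6-fold lower for Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, on 261 and 3 UMIs [20.2 to 291], to 25.6-fold for Col4a3. Of these 23 genes, 18 moved by over 1.5 times in at least 1 other setting, with no change of direction. The log2 fold ranged over settings from 7.05 to 11.70 for Aif1l, 7.57 to 9.76 for Hhipl1, 6.98 to 9.62 for Kcnk5, 5.68 to 7.54 for Ptgfrn, 6.76 to 7.84 for Ankrd1, 6.45 to 10.85 for Sh3d19, 5.65 to 7.08 for Pkhd1, 6.29 to 8.70 for Sh3rf1 and 5.91 to 7.01 for H19. Among the lowest it ranged from -6.26 to -3.59 for Dhrs7c, -6.26 to -3.07 for Stc2, -5.57 to -4.20 for Mybpc2, -5.19 to -3.93 for Lrrc38, -5.18 to -4.31 for Myoz1, -5.06 to -3.79 for Mylk4, -4.95 to -4.21 for Rpl3l, -4.84 to -4.03 for Asb18 and -5.31 to -3.36 for Col4a3. Rpl3l, a muscle form of a ribosomal protein, was 28.6-fold lower [23.3 to 35.5], and Myoz1, a Z-disc protein of fast fibres, 32.8-fold lower [27.4 to 39.5]. Of the genes named here, 5 lie on GRCm38 as annotated by GENCODE vM21 as follows: Runx1 (ENSMUSG00000022952) on chromosome 16 from 92601466 to 92826149, Fbxo32 (ENSMUSG00000022358) on chromosome 15 from 58175879 to 58214932, Myh4 (ENSMUSG00000057003) on chromosome 11 from 67238029 to 67260446, Maf (ENSMUSG00000055435) on chromosome 8 from 115682942 to 115707794, and Mylk4 (ENSMUSG00000044951) on chromosome 13 from 32700834 to 32783954. Myh4 lies on the plus strand and the others on the minus strand.

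**Figure D4:**
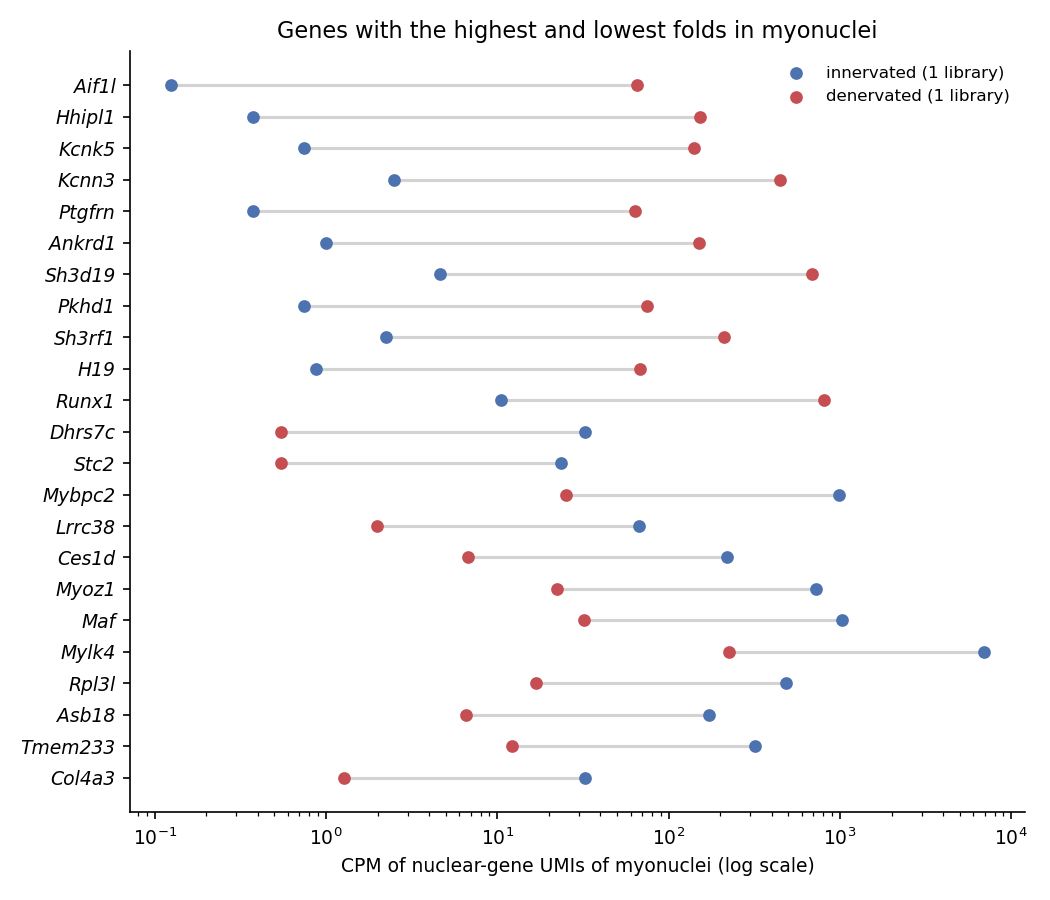
Level in myonuclei, in CPM on a log axis, of genes with the highest and the lowest folds, innervated library in blue and denervated library in red. Runx1 stood at 10.6 and 807 CPM and Mylk4 at 6960 and 226 CPM.

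The third comparison asked whether nuclei with a Myh4 majority differ from those with a Myh2 majority, the only majority classes with at least 100 nuclei in each library (3103 and 139, and 177 and 105). Denervated Myh4-majority nuclei are those that retained Myh4, and the difference between classes was not tested. Over nuclei, Myh4-majority nuclei had a median of 7 innervated and 6 denervated Myh4 UMIs, and Myh2-majority nuclei 9 and 11 Myh2 UMIs beside 2 and 1 Myh1 UMIs, with medians of 0 for the remaining isoforms. The median depths were 1680 and 4734 UMIs in Myh4-majority and 1578 and 3470 UMIs in Myh2-majority nuclei, so equal medians are not equal levels. Myh4-majority nuclei lay mostly in clusters 0, 1 and 2 in the innervated and 3 and 9 in the denervated library, and Myh2-majority nuclei in clusters 7 and 9. Of 16 fast sarcomere genes measured in Myh4-majority nuclei 13 were at least 1.5-fold lower and 0 higher, with a median log2 fold of -1.66 [-1.80 to -1.49]. In Myh2-majority nuclei 11 of 15 were lower and 4 higher, with a median of -0.93 [-1.06 to -0.66]. The 4 higher ones were Myl1 at 2.36-fold [2.09 to 2.67], Mylpf at 2.22-fold [1.30 to 3.99], Tpm1 at 1.56-fold [1.33 to 1.84] and Actn3 at 1.58-fold [0.994 to 2.57]. Medians of the other lists rest on members that differ between the classes. Glycolysis genes stood at -1.76 over 26 genes and -0.96 over 19, mitochondrial genes at -1.47 over 31 and -1.33 over 29, and slow sarcomere genes at 1.72 and 0.04 over 8 each, which were 2.95 and -0.29 at a limit of 80%. Denervation regulators stood at 1.74 over 13 genes and 2.99 over 6 genes, the latter 2.04 at a limit of 80%. Fbxo32 was 10.4-fold higher [9.66 to 11.2] in Myh4-majority and 3.37-fold higher [2.72 to 4.20] in Myh2-majority nuclei, and Trim63 2.96-fold [2.81 to 3.12] and 1.82-fold higher [1.58 to 2.11]. Their innervated levels were 203 and 318 CPM for Fbxo32 and 815 and 809 CPM for Trim63.

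The genes whose fold in Myh4-majority nuclei lay furthest above that in Myh2-majority nuclei were Myom3, an M-band protein of slow and oxidative fibres (203-fold and 3.96-fold higher), Egln3, an oxygen-sensing hydroxylase (9.77 CPM innervated and 58.6 CPM denervated in Myh4-majority nuclei, 355 and 51.8 CPM in Myh2-majority nuclei), Zfp697, Kcnn3, Arpp21 and the cystine carrier Slc7a11. Those furthest below were the carbonic anhydrase Car3 (0.184 of the innervated level and 4.69-fold higher), the actin-binding Xirp2 (0.333 of it and 2.56-fold higher), Slc4a4, Hectd2os, Ltbp1 and the insulin receptor substrate Irs1. Innervated Myom3 stood at 2.12 CPM in Myh4-majority and 176 CPM in Myh2-majority nuclei, and denervated Myom3 at 430 and 697 CPM.

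**Figure D5:**
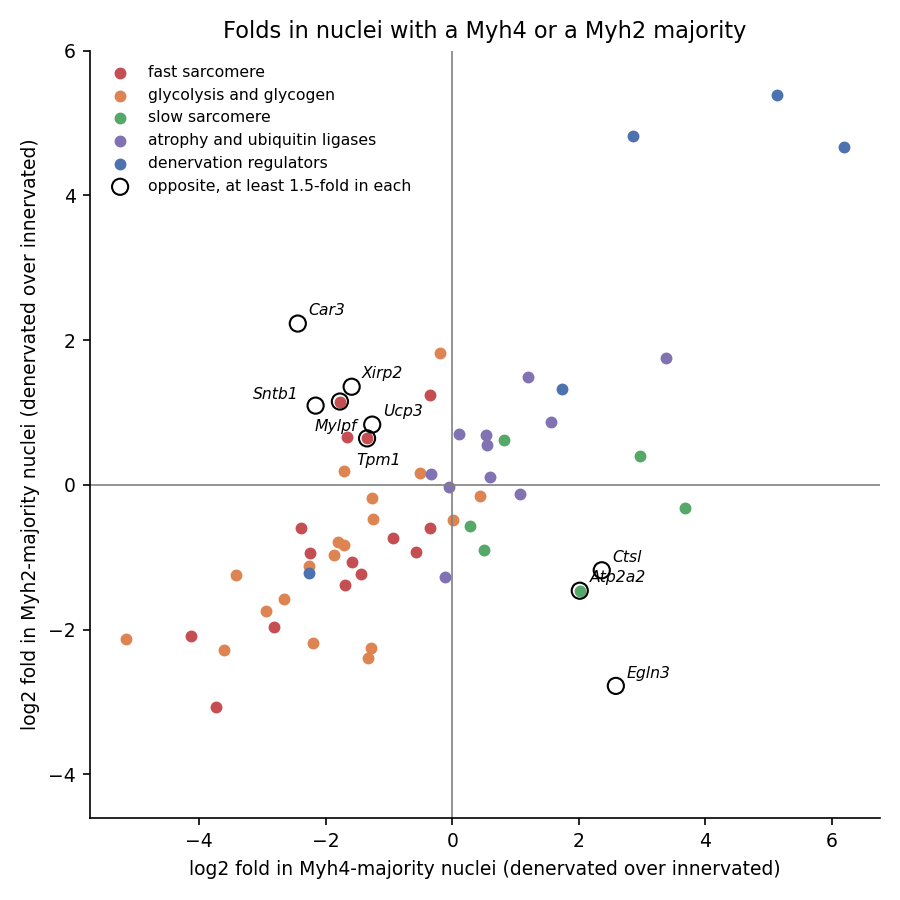
Log2 fold, denervated over innervated, in Myh2-majority nuclei against that in Myh4-majority nuclei for genes of 5 lists, each point a gene measured in both classes. Ringed genes, from any list or the named genes, were at least 1.5-fold higher in one class and at least 1.5-fold lower in the other, such as Car3 and Egln3.

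At the neuromuscular junction, the nuclei of the junction-like cluster numbered 62 (1.44% of myonuclei) in the innervated and 24 (2.02%) in the denervated library; induction outside the synapse can move nuclei between clusters, so these sizes carry that limit. Outside the cluster Musk stood at 169 and 992 CPM, while inside it stood at 1781 CPM [1582 to 1998] and 1788 CPM [1550 to 2051]. Ncam1 was 118-fold higher outside [86.1 to 168] and 1.98-fold higher inside [1.72 to 2.29]. Colq, Etv5 and Chrne were 9.13-fold, 3.31-fold and 2.51-fold lower inside the cluster that they help to define, while outside it Colq was 23.1-fold higher on 3 and 51 UMIs [7.48 to 116] and Etv5 4.63-fold higher on 5 and 17 UMIs [1.64 to 16.0]. Runx1 was 16.4-fold higher inside [8.83 to 33.6] and 101-fold higher outside. The myotendinous junction-like cluster, marked by Col22a1, held 249 innervated (5.77%) and 23 denervated nuclei (1.94%).

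In fibro-adipogenic progenitors, matrix and activation genes had a median log2 fold of 0.49 [0.31 to 0.83], with 6 of 16 at least 1.5-fold higher and 0 lower. The matrix proteins Tnc, Postn and Fn1 were 12.7-fold [4.87 to 42.1], 8.40-fold [3.33 to 25.2] and 2.08-fold higher [1.54 to 2.80]. By size, the highest were Chl1, a neural adhesion molecule, 65.8-fold higher on 2 and 60 UMIs [17.4 to 555], Tmem267, Col28a1, Tnc and Nrros, and the lowest Ret, the receptor chain for the neurotrophic factor Gdnf, 5.75-fold lower [2.34 to 18.3], Il15, Plod1, Col15a1 and Zfp64. Il15 was lower in myonuclei as well, by a log2 fold of -2.99. The macrophage markers F13a1 and Adgre1 were higher in the same nuclei, 4.05-fold on 20 and 37 UMIs [2.29 to 7.37] and 12.1-fold on 2 and 11 UMIs [2.63 to 112]. Nrros is a gene of macrophages and also led the macrophage-like cluster, and Col15a1 is a class marker. RNA of muscle fibres was abundant in these nuclei, with Ttn at 23517 CPM innervated and 8256 CPM denervated, 41.6% and 24.2% of the myonuclear level, so genes that myonuclei express cannot be read in them. The share of free RNA in their UMIs, estimated from Ttn, Neb and Trdn, was 46.3% innervated and 28.2% denervated. Such a difference in dilution alone makes a gene absent from free RNA 1.34-fold higher (log2 0.42), near the matrix median of 0.49. The estimate in myonuclei, from markers of other cell types, was 11.5% and 13.1%. These estimates move in opposite directions between the libraries, so neither is a firm measure of free RNA. Satellite cell-like nuclei were few, and their 4 measured state genes had a median of 0.25 [-0.61 to 0.71].

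A ribosomal-like transcript, Gm42418, was higher in each class, from 1.96-fold in blood endothelial nuclei to 4.69-fold in satellite cell-like nuclei and 2.48-fold in myonuclei, and its share of all UMIs was 4.71% in the innervated and 13.04% in the denervated library. The same held for Cdk8, which overlaps such sequence in droplet data, at 4.81-fold in myonuclei and 6.88-fold in fibro-adipogenic progenitors. Both were chosen after their values were seen.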

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

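The tests of nuclei counted in another class, the count of genes under 1.5-fold at a limit of 80% and the bounds applied to the fast and glycolysis genes were chosen after the results had been seen. The limit of 80%, thinning and the subtraction of free RNA were settings chosen before the data were examined. Among list members and named genes, 9 moved at least 1.5-fold in opposite directions in Myh4-majority and Myh2-majority nuclei with both counting intervals on opposite sides of 1, and the difference itself was not tested, since each condition had 1 library. Higher in Myh4-majority and lower in Myh2-majority nuclei were Egln3, an oxygen-sensing hydroxylase, with a difference of log2 folds of 5.36, the lysosomal protease Ctsl with 3.54 and the slow calcium pump Atp2a2 with 3.48. Lower in Myh4-majority and higher in Myh2-majority nuclei were the carbonic anhydrase Car3 with a difference of -4.67, the membrane adaptor Sntb1 with -3.25, the actin-binding Xirp2 with -2.95, the fast myosin light chain Mylpf with -2.93, the mitochondrial carrier Ucp3 with -2.10 and the tropomyosin Tpm1 with -1.99. In the denervated library, Egln3, Atp2a2, Tpm1 and Ucp3 were not above the other class, beyond counting error, in the class where they rose. Their opposite folds thus rest on unlike innervated levels.

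Nuclei of another majority class that were counted in a class after denervation could bring that class's levels with them, and so yield opposite folds. For 1 gene, Xirp2, nuclei that kept the innervated levels of their class cannot be the whole cause. Its denervated level in Myh2-majority nuclei, 1787 CPM, lay above that of every innervated majority class, by 1.68-fold over the highest [1.57 to 1.81]. Nuclei of another class whose own Xirp2 level had changed with denervation were not tested and stay possible. For the remaining 8 genes no denervated level lay outside those of the innervated classes beyond counting error. Nuclei of another class remain a possible explanation for them. This holds for Car3 too, which at 376 CPM lay below the 990 CPM of the 13 innervated Myh7-majority nuclei. Nuclei of mixed myosin content near the limit are weakly argued against for 7 genes, which were at least 1.5-fold each way at a limit of 80%. All 9 genes kept opposite directions at that limit. It left fewer than 100 Myh2-majority nuclei in each library. Nuclei of the 2 classes had medians of 6 to 13 myosin UMIs, so a nucleus above 80% can still be mixed. For the other 2 genes, Ctsl (log2 -0.13 in Myh2-majority nuclei) and Sntb1 (0.58), mixed nuclei stay open. A fibre-type-dependent response to denervation is left as a hypothesis. It rests on 1 library per condition, with nuclei classed by the myosin they retained. For none of the 9 genes can this response be told apart from nuclei of another class.

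Fast sarcomere and glycolysis genes were lower in denervated myonuclei, with medians of -1.86 and -2.23 on the log2 scale. Fewer nuclei of Myh4 fibres among the denervated myonuclei are argued against as the whole cause, since within Myh4-majority nuclei the smaller of the 2 medians was -1.66, although those nuclei were selected on retained Myh4 and could include nuclei of other classes. Free RNA that differs between the libraries was left undecided by the smaller median of -1.84 after expected free RNA had been subtracted. The subtracted profile was the sum of all barcodes of a library, in which myonuclei were the largest class. Its subtraction could thus move these folds little. The -1.88 after thinning could not decide on unequal depth, because thinning keeps the proportions within each nucleus on average. By the same reasoning, depth alone would not shift a fold of summed shares on average while the same nuclei are kept and named. Depth could still act through which nuclei are kept and named. The gap was not shared by all classes, with median UMIs of 1551 and 3578 in myonuclei but 1340 and 1357 in fibro-adipogenic progenitors. A difference in preparation between the 2 libraries is confounded with the condition and also stays open, as does denervation itself.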

How the results depend on the processing

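No paired analysis was possible because each condition had 1 library of pooled muscles, so there was no replicate to leave out and no other split of samples. Settings added after the data had been seen were the unnamed cluster kept in the myonuclei and 3 ribosomal-like transcripts left out of the total. Across 183 values of the main results under other settings, 134 stayed inside the counting interval and 49 moved outside it, and no log2 fold among them changed sign. The 183 include shares of nuclei, which cannot change sign. They also include settings that could not alter a value, such as list minima for the fold of Myh4. Of 791 values of single genes and other lists, 695 stayed inside and the rest moved outside, and 11 changed sign. Apart from autophagy and the median of all genes, these were lists whose interval held 0: matrix genes in myonuclei (-0.11 with at least 1000 UMIs per nucleus, -1.55 after thinning and -1.86 at a minimum of 50 UMIs), the free RNA list in Myh4-majority nuclei (-0.14 at a limit of 80% and -0.02 with TMM factors), autophagy (-0.08), slow (-0.29) and sex-linked genes (-0.04) in Myh2-majority nuclei at 80%, and immediate early genes in fibro-adipogenic progenitors (-0.12 without doublet removal). The genes named in myonuclei as highest or lowest kept their direction under every setting run on them. A minimum of 200 UMIs changed nothing, since the lowest deposited barcode held 500. Depth limits some lists in the smaller classes, where 6 of 20 denervation regulators in Myh2-majority nuclei and 4 of 18 state genes in satellite cells reached 20 UMIs.

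On the log2 scale, TMM factors gave -2.27 for glycolysis in myonuclei and -1.82 for the fast list in Myh4-majority nuclei, and DESeq2 factors -2.34 for glycolysis, -1.18 for mitochondria and -3.62 for Myh4. Equal weight per nucleus gave 1.53 for the slow list and -3.58 for Myh4. With at least 1000 UMIs per nucleus the fast list stood at -1.78, glycolysis at -2.16 and Myh4 at -3.43, myonuclei were 70.2% of the innervated library, fibro-adipogenic progenitors 8.21% and 6.59%, and 83.1% of innervated nuclei with enough myosin had a Myh4 majority. Without doublet removal glycolysis stood at -2.16, Myh4 at -3.43 and denervated myonuclei at 53.7%. Thinning gave 1.14 for denervation regulators, 0.66 for atrophy genes, 1.58 for the slow list, -2.25 for glycolysis and 24.4% of denervated nuclei with a Myh4 majority.

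Majority classes at their innervated shares gave 0.80 for postsynaptic genes, -1.59 for the fast list, 0.51 for the slow list, -1.78 for glycolysis, -1.28 for mitochondria and -1.49 for Myh4, and turned autophagy to -0.014. By construction this setting holds fixed the shares of classes that Myh4 itself defines. Nuclei with fewer than 3 myosin UMIs were kept as a class of their own, also at its innervated share. Without a minimum for list members, denervation regulators stood at 1.07 and glycolysis at -2.16, because thinly covered members entered. With the unnamed cluster kept, glycolysis stood at -2.15 and denervated myonuclei at 72.6%, which its own nuclei add. With the ribosomal-like transcripts out, the fast list stood at -1.74, glycolysis at -2.11, mitochondria at -0.95 and Myh4 at -3.38, and the median of all genes moved from -0.10 to 0.02, against -0.22 with DESeq2 factors.

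Leiden resolution 0.5 gave 72.9% denervated myonuclei, 1.08% and 5.21% macrophages and 18.8% denervated fibro-adipogenic progenitors, and resolution 2 gave 62.4% denervated myonuclei and 4.78% macrophages. Separate clustering gave 65.1% denervated myonuclei, 0% and 5.21% macrophages and 15.2% denervated fibro-adipogenic progenitors. A limit of 80% put 83.3% of innervated nuclei in the Myh4 majority, and at least 10 myosin UMIs put 74.7% and 25.9% there. Where no construction is named, the cause was not tested.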

Other observations

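The test of the hour of collection in this part was chosen after the result had been seen. Genes that support nerve and Schwann cells went both ways in myonuclei. Among factors acting on nerve, 4 of 11 measured genes were at least 1.5-fold higher and 5 lower, with a median log2 fold of -0.22. The transmembrane semaphorin Sema6a was 46.0-fold higher [29.9 to 74.9] and Gdnf, a survival factor for motor neurons, 3.41-fold higher on 12 and 28 UMIs, while the growth factor Igf1 was 8.90-fold lower [5.82 to 14.3]. Of Schwann cell repair genes, 3 of 5 were higher in myonuclei and 1 lower, with a median of 0.93, and of Schwann cell myelin genes 2 of 4 were higher and 0 lower, with a median of 1.02, which was 2.51 after thinning, 1.69 at a minimum of 50 UMIs and 0.55 when list members of any depth were kept. Mbp, the myelin basic protein gene, which muscle also transcribes in part, was 14.3-fold higher. Gdnf and Ncam1 are also in other lists, and no Schwann cell cluster was found.

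Satellite cell state genes had a median log2 fold of 1.87 [1.55 to 2.67] in myonuclei, with 5 of 7 higher and 1 lower, such as Megf10 at 32.4-fold, the proteoglycan Sdc4 at 8.77-fold and Pax7, a stem cell factor, at 3.65-fold. That median was 3.24 after thinning and 1.13 when list members of any depth were kept. Polyamine genes had a median of -0.17 (-0.56 at innervated class shares), with 1 of 9 higher and 2 lower. The spermine oxidase Smox was 16.2-fold lower and Amd1, which supplies the donor for polyamine synthesis, 3.68-fold lower, while Odc1, the first enzyme of the pathway, was 3.45-fold higher. Immediate early and heat shock genes, read as signs of handling, had 4 of 8 higher and 2 lower, with a median of 0.50 (0.77 with at least 1000 UMIs per nucleus and 0.84 with at most 2% mitochondrial UMIs), led by the stress factor Atf3 at 58.4-fold on 5 and 200 UMIs. The sex-linked list had 2 measured genes, Xist at 1.09-fold and Tsix at 2.00-fold, with a median of 0.56, or 1.27 when list members of any depth were kept. Matrix genes of fibroblast-like cells had a median of 0.39 in myonuclei over 8 thinly covered genes, but -1.55 after thinning and -1.86 at a minimum of 50 UMIs.

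Clock genes had a median log2 fold of -0.28 in myonuclei (-0.54 after thinning), with 4 of 14 higher and 5 lower. The activators of the loop were higher, Arntl at 2.41-fold, Clock at 3.20-fold and Npas2 at 5.46-fold, while Per3, Ciart and Tef were 2.81-fold, 6.03-fold and 1.76-fold lower. Activators minus their targets gave a contrast of 2.25 [2.05 to 2.42] on the log2 scale. A different hour of collection of the libraries is a candidate explanation, and would shift the clock in other cells of the muscle too. In fibro-adipogenic progenitors the contrast was 0.91 [0.35 to 1.41]. Free RNA alone, at the share estimated there from muscle fibre genes, was expected to bring 0.82. The hour of collection and denervation therefore cannot be told apart here.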
